A study of Homo sapiens with 5 samples.

How the data were processed

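Gene expression was measured by RNA-seq of polyadenylated RNA from HCT116 cells, in 3 control libraries and 2 libraries of cells treated with LT4. Per the labels' protocols, RNA was extracted with TRIzol and libraries were made with a TruSeq stranded mRNA kit, which selects poly(A) RNA and keeps the strand. Per the submitters' processing notes, fastp 0.20.0, HISAT2 2.1.0, SAMtools 1.9, featureCounts and Subread 2.0.1 were used with GRCh38; the notes give no order or settings. The annotation release, the strand setting of the counting and any filter are not given in the sources used here, so antisense and overlapping genes may share reads, and near-identical histone and mitochondrial-like copies are uncertain.

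The deposited table holds, per the file headers, raw read counts per Ensembl gene for each library. Per the file headers it also holds TPM values for each library, which the authors scaled to a sum of 1000000 per library; TPM was used here only for a check. In every library genes with a count of 0 also had a TPM of 0. The authors also deposited log2 fold changes, p-values and adjusted p-values of each LT4 library against the controls, with values for 14970 genes; neither headers nor labels name their test, and they are reported only as the authors' values. A further 2 columns of per-sample values and 3 comparison columns match no sample analysed here and were not used.

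Groups came from the sample titles. Gene symbols came from a reference name table, in which 60295 of 60623 gene IDs matched, and biotypes, positions and exon lengths from GENCODE 29 (GRCh38), which held 58516 of the IDs. Analyses used R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.

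The test of LT4 against control was edgeR's quasi-likelihood F test on the counts of all 5 libraries, after edgeR's expression filter and TMM scaling, with robust dispersion, group as the only term and Benjamini-Hochberg adjustment over the 13833 genes tested at a threshold of 0.05. The biological coefficient of variation was 14.6%. Standard errors are the absolute log2 fold change divided by the square root of F. CPM values are TMM-scaled except the shares of RNA classes, which are of the library total. Limits for a count of 0 are 3 counts of the library total, and cover counting error only. The interval of a list's median came from a bootstrap over its members and covers the spread between them. Single-library comparisons assume that the lone LT4 library varies like the controls.

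The gene lists (36 lists, 977 members, of which 1 matched no gene), the tests and the first set of alternatives were fixed before the data were examined. They cover PI3K-AKT-mTOR and MAPK signalling, stress responses, metabolism, cell cycle, cell death, migration, immune and colon genes, growth, histones as a sign of RNA selection, and markers of fibroblasts, leukocytes and hepatocytes. The 33 lists with at least 5 tested members were tested with camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists, and beside it with an estimated correlation and with fry. With the preset correlation 17 lists passed (9 higher, 8 lower), with an estimated correlation 0, and by fry 5 (4 higher, 1 lower). Values by fry are of its directional test unless its mixed test, which asks whether members moved either way, is named. Camera asks whether a list moved relative to other genes.

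Genes were named by a rule fixed in advance: among protein-coding genes past the threshold with a mean log2 CPM of at least 2 and both LT4 libraries beyond all controls, the 10 largest rises and falls and the 10 smallest p in each direction; for each list past the camera threshold the 4 members with the smallest p, and for each other list with a member past the threshold the 2 with the smallest p; and genes of prior interest, among them PIK3CG, PIK3CA, AKT1, MAPK3, CDKN1A, MYC, CCND1, CDH1, VIM and MMP9. Some genes that the rule covers and 1 of the 17 lists that passed are not reported here. Other genes are said to be named after their values were seen.

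That first set held RLE size factors, library totals only, no count filter, at least 50 counts in at least 2 libraries, leaving out each library, a replicate block, DESeq2, limma voom, an adjusted p under 0.01, and the other list tests. Added after the data were seen were protein-coding genes only (without mitochondrial and histone genes), per-library loess trends on gene length or GC content (span 0.5) as offsets, all libraries thinned to the total of LT4 replicate 3, and 5 further gene lists. Length was known for 99.6% of tested genes and GC content for 99.6%. Library properties were compared with an exact permutation test over 10 splits. Groups of 3 and 2 libraries are too small for the test of single outlying libraries and for counts over other splits.

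The analysis was tested on simulated counts with the means of the real controls, the real library sizes and 200 changed genes. The changed genes were drawn only from those above a minimum mean in controls. How often changes of scarcer genes, such as RICTOR (1.88 CPM in controls), are called was therefore not measured. For LT4 against control (13465 simulated genes) 28% of genes changed 1.5-fold, 84% of those changed 2-fold and 94% of those changed 3-fold were called, and 8.38% of calls were on unchanged genes. For single libraries, 2-fold changes were called for 74% in LT4 replicate 1 (13662 genes) and 52% in LT4 replicate 3 (13675 genes), with 15.2% and 14.7% of calls on unchanged genes. A list raised 1.5-fold passed under all 3 list tests, and of 32 unchanged lists 0, 0 and 1 passed with the preset correlation, the estimated correlation and fry. Simulated genes varied independently of each other. In the real libraries the estimated correlation between members was 0.148 for the ATF4 and integrated stress response list and 0.538 for ribosomal proteins. The simulation therefore cannot show how the list tests behave where members vary together.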

Results

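RNA-seq was done on HCT116 cells, an established human colorectal carcinoma cell line. The libraries fell into 2 groups, controls (replicates 1, 2 and 3, n = 3; the labels say nothing more of them) and cells treated with LT4 (replicates 1 and 3, n = 2). The series title names the compound as 4-acetylantrocamol LT3 while the design text and the sample titles say LT4, and the labels give neither the dose nor the time of treatment. Per the study's design text, the question was how LT4 acts on colorectal cancer cells, and its title names the PI3K/AKT and MAPK pathways. The table holds read counts for 60623 genes. Total counts were 12296916, 11954776 and 11653484 in controls 1, 2 and 3, 9840467 in LT4 replicate 1 and 2281912 in LT4 replicate 3. Nothing in the labels says that replicates came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. The file headers place each LT4 library in a group of its own, so it is also not stated that LT4 replicates 1 and 3 received the same treatment.

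LT4 replicate 3 stood apart from the other libraries. It had 16770 genes with at least 1 count, against 19492 to 20203 in the controls and 19377 in LT4 replicate 1, and mitochondrial genes took 9.92% of its counts, against 5.83% to 6.64% in the controls and 5.73% in LT4 replicate 1. The total count was 11970000 ± 321900 (SD, n = 3) in controls and 6061000 ± 5345000 (SD, n = 2) with LT4 (exact permutation test, two-sided, p = 0.1, adjusted p = 0.2 over 4 properties). The exact permutation p was 0.1 for genes detected, 0.5 for the mitochondrial share and 0.4 for the share taken by the 10 highest genes, and 0.1 is the smallest p that the 10 splits of 5 libraries allow. The first principal component (51.4% of the variance) placed LT4 replicate 3 at 31.3 and the other libraries between -15.1 and -2.91, and the component after it (31.7%) placed LT4 replicate 1 at 23.2 and the others between -13.9 and 1.78. Neither axis separated the groups as a whole. Pearson correlations of log2 CPM (counts scaled to a library sum of 1000000) across genes were 0.985 to 0.988 between controls and 0.958 between the LT4 libraries. Genes are not independent replicates, so these values only describe the libraries. No pair of libraries was as alike as repeated sampling of 1 library, with a chi-square per degree of freedom of 5.53 or more in every pair. By this measure the LT4 libraries were the least alike pair (30), above LT4 replicate 3 against any control (17.8 to 22.9). Control 1 and LT4 replicate 1 had a Pearson correlation of 0.986.

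In the LT4 libraries 17 genes were higher and 2 lower than in the controls. CHAC1, which encodes a glutathione-degrading enzyme induced by the transcription factor ATF4 (ENSG00000128965, GRCh38 chromosome 15, 40952962 to 40956519, protein-coding), had the largest rise, from 12.6 ± 0.448 CPM in controls (SD, n = 3) to 49.1 ± 0.654 CPM with LT4 (SD, n = 2). Its log2 fold change was 1.96 (SE 0.16, adjusted p = 0.000129). CRABP2, a cytoplasmic carrier of retinoic acid (ENSG00000143320, chromosome 1, 156699606 to 156705816), fell from 578 ± 38.2 to 281 ± 32.1 CPM (log2 fold change -1.04, SE 0.14, adjusted p = 0.0175). KRT13, a keratin of stratified epithelia (ENSG00000171401, chromosome 17, 41500981 to 41505705), fell from 45.6 ± 5.06 to 20.1 ± 0.707 CPM (log2 fold change -1.17, SE 0.17, adjusted p = 0.0175). Of 13833 genes tested with edgeR's quasi-likelihood test, 19 passed an adjusted p of 0.05, and 13 of them changed at least 2-fold. Both LT4 libraries lay above every control for 2398 of the genes tested (17.3%) and below every control for 2289 (16.5%). Chance gives 10% in each direction only if all libraries are alike, and LT4 replicate 3 differed in depth and RNA composition. These shares therefore do not by themselves show a response to LT4.

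The other genes that rose did diverse work. FBXO30, a ubiquitin ligase subunit, rose by a log2 fold change of 1.74 (SE 0.27, adjusted p = 0.0239), and SLC7A11, the cystine importer, by 1.51 (SE 0.25, adjusted p = 0.0368). CLIC4, an intracellular chloride channel protein, rose by 1.48 (SE 0.21), CPA4, a secreted carboxypeptidase, by 1.31 (SE 0.19), and UPP1, a uridine phosphorylase, by 1.11 (SE 0.15), each with adjusted p = 0.0175. NT5E, the cell-surface enzyme that makes adenosine (CD73), rose from 5.54 ± 0.305 to 14.8 ± 2.46 CPM (log2 fold change 1.37, SE 0.22, adjusted p = 0.0321). AKAP12, a kinase-anchoring scaffold, was the most abundant gene that rose, from 386 ± 59.7 to 815 ± 106 CPM (log2 fold change 1.08, SE 0.15, adjusted p = 0.0175). STC2, TRIB3, PSAT1 and PCK2 rose by 1.05, 1.01, 1.04 and 0.98, and TXNRD1 and FOSL1 by 0.88 and 0.79. AHNAK2 (0.87), the receptor kinase AXL (0.85) and the retinaldehyde dehydrogenase ALDH1A3 (0.75) completed the 19 and are named here after their values were seen. The count depended on which libraries entered: CHAC1 alone passed without control 1, without control 2 or without control 3, while 598 genes passed without LT4 replicate 1 and 526 without LT4 replicate 3, where the spread came from the controls alone. All 19 genes passed with either LT4 library left out.

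**Figure D1:**
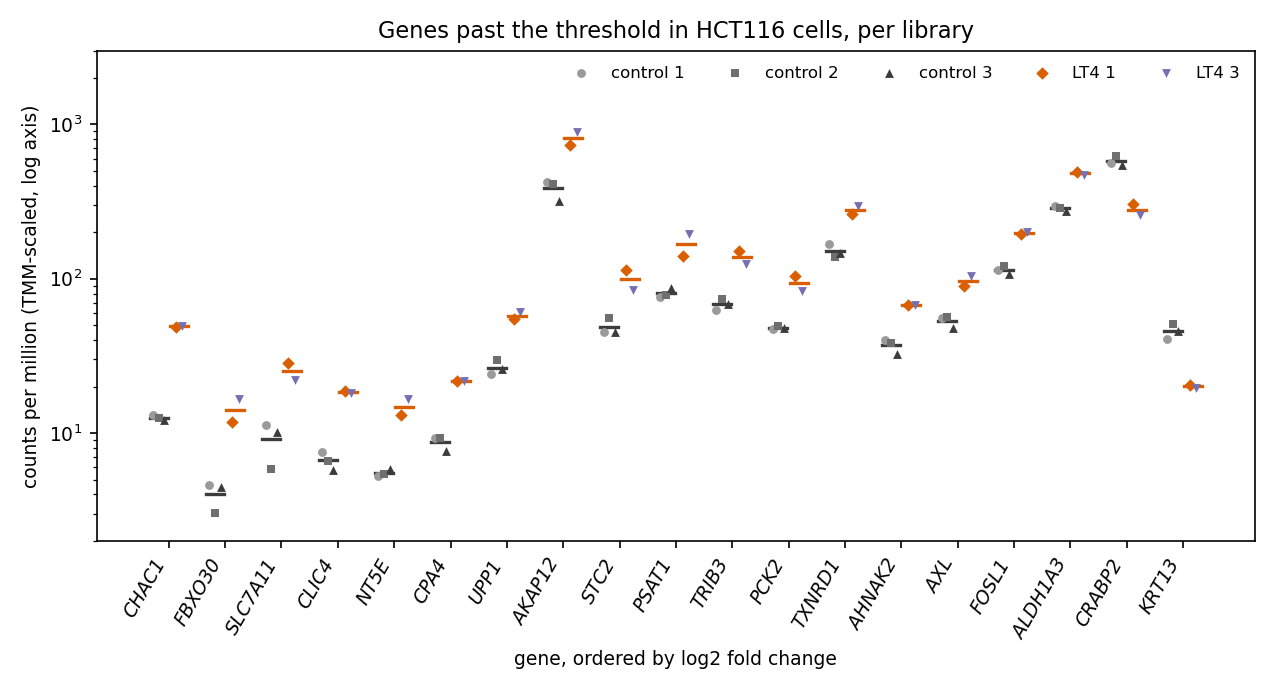
CPM (TMM-scaled, log axis) of the 19 genes past the threshold in each of the 5 libraries, ordered by log2 fold change, with a horizontal line at each group's mean. Both LT4 libraries lie beyond all 3 controls for each gene, from CHAC1 (49.1 against 12.6 CPM) to KRT13 (20.1 against 45.6 CPM).

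Genes of the integrated stress response, the programme of amino acid supply and stress genes run by ATF4, were higher as a list by camera with a preset correlation (adjusted p = 1.92e-25 over 33 lists) and by fry (0.0381), which asks whether the members moved one way on balance, but not with an estimated correlation (adjusted p = 0.254). Of 31 measured members, 6 rose over all genes tested (CHAC1, TRIB3, PCK2, PSAT1, STC2 and SLC7A11) and none fell; adjusted over the list alone, 22 rose. TRIB3, a pseudokinase induced by ATF4, went from 68.8 ± 5.73 to 138 ± 18.9 CPM. PCK2, the mitochondrial PEP carboxykinase, went from 48.1 ± 1.16 to 94.2 ± 15.1 CPM and PSAT1, of serine synthesis, from 80.7 ± 5.33 to 167 ± 38.5 CPM. Members that did not pass over all genes included SLC3A2 (log2 fold change 0.62, adjusted p = 0.0833), SLC7A5 (0.73, adjusted p = 0.109) and SESN2 (0.62, adjusted p = 0.117). SLC7A5 passed with LT4 replicate 1 alone (1.03, adjusted p = 6.11e-07) and not with LT4 replicate 3 alone (0.35, adjusted p = 0.139). ATF4 itself (0.47, adjusted p = 0.124), ASNS (1.69, adjusted p = 0.134) and DDIT3 (0.62, adjusted p = 0.28), named after their values were seen, also had positive values. ASNS was scarce, at 0.94 CPM in controls and 2.82 CPM with LT4, near the 1.31 CPM that 3 counts make in LT4 replicate 3. CTH (-0.49), PSPH (-0.17) and SHMT2 (-0.03), likewise named afterwards, had negative values. The list's median log2 fold change was 0.62, and both LT4 libraries lay above all controls for 25 members and below all controls for 2. With LT4 replicate 1 alone, 18 members rose and the median was 0.59, and with LT4 replicate 3 alone 11 rose and the median was 0.58.

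The series title names PI3K/AKT and MAPK signalling, for which 4 lists had been fixed. None of the 33 measured PI3K-AKT-mTOR components passed over all genes or adjusted over the list alone (0 genes each). Among them RICTOR had the smallest p (log2 fold change 1.48, SE 0.39, adjusted p = 0.133), followed by PIK3C2A (0.96, SE 0.27, adjusted p = 0.148), PDPK1 (0.47, adjusted p = 0.25) and FOXO3 (0.41, adjusted p = 0.285). Values were 0.77 (SE 0.37, adjusted p = 0.379) for PIK3CA and 0.03 (SE 0.16, adjusted p = 0.953) for AKT1. AKT1 had 0.26 with LT4 replicate 1 alone and -0.26 with LT4 replicate 3 alone. PDPK1 had 0.62 (adjusted p = 0.0352) and 0.21 (adjusted p = 0.672) in the same order. PIK3CG, which encodes the PI3K gamma subunit, had 1 count in control 1 and 0 in the other 4 libraries, where a count of 0 allows up to 0.305 CPM in LT4 replicate 1 and 1.31 CPM in LT4 replicate 3. The median of the list was 0.18, with camera adjusted p = 0.0147 (higher), adjusted p = 0.435 with an estimated correlation and 0.158 by fry. That call was not met without LT4 replicate 1 (0.471), with the gene-length trend between libraries removed (0.392), at equal depth (0.12) or with a stricter count minimum (0.0616). With LT4 replicate 1 alone, 4 members passed as higher, and with LT4 replicate 3 alone none did. At an unadjusted p under 0.05, edgeR gave 4 higher and 0 lower members, and DESeq2 and limma voom called 0.

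The 35 measured MAPK components gave no call over all genes or adjusted over the list alone (edgeR, with 5 higher and 1 lower at an unadjusted p under 0.05, and 0 calls by DESeq2 and limma voom), with a median of 0.08 and camera adjusted p = 0.543 (0.804 with an estimated correlation, 0.526 by fry). By fry's mixed test, which counts moves both ways, the adjusted p was 0.0383. For PI3K-AKT-mTOR components it was 0.0536, for FOXO-responsive genes 0.056 and for the ERK-responsive genes described below 0.0104. The direction of the MAPK list turned between the LT4 libraries. The median was 0.09 with LT4 replicate 1 alone (camera adjusted p = 0.187, higher, 0 members called). It was -0.09 with LT4 replicate 3 alone (0.471, lower, 1 member higher and 1 lower). MAPK3 (ERK1) had a log2 fold change of -0.30 (SE 0.15, adjusted p = 0.392), with -0.18 and -0.44 in LT4 replicates 1 and 3 alone. The FOXO-responsive list, whose members rise when AKT is off in many cell types, had 22 measured members and no call in either count (2 higher and 1 lower at an unadjusted p under 0.05, and 0 by DESeq2 and limma voom). Its median was -0.10, its mean 0.00 and its camera adjusted p 0.933 (lower), with adjusted p = 0.932 with an estimated correlation and 0.822 by fry, which pointed higher.

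ERK-responsive genes, transcripts that follow ERK activity in many cell types, were higher as a list by camera with a preset correlation only (adjusted p = 1.77e-07), with adjusted p = 0.281 with an estimated correlation and 0.0983 by fry. FOSL1, a subunit of the AP-1 transcription factor, rose from 114 ± 6.71 to 197 ± 4.71 CPM and was the 1 of 26 members past the threshold over all genes by edgeR (4 by DESeq2), and 11 rose adjusted over the list alone. EREG, a ligand of the EGF receptor (0.85, SE 0.17, adjusted p = 0.0759), the cytokine gene LIF (0.74, SE 0.15, adjusted p = 0.0813), the ERK pathway inhibitor SPRED1 (0.92, SE 0.23, adjusted p = 0.117) and CCND1, or cyclin D1 (0.50, SE 0.13, adjusted p = 0.117), came next. Of the 26 members 25 had a positive value, both LT4 libraries lay above all controls for 16, and the median was 0.40. Some members hardly moved, among them DUSP6 (0.05, adjusted p = 0.931), ETV4 (0.06, adjusted p = 0.901) and PHLDA1 (0.08, adjusted p = 0.826). EGR1 had 0.09, with 0.45 in LT4 replicate 1 alone and -0.78 in LT4 replicate 3 alone. These genes are named after their values were seen. With LT4 replicate 1 alone 6 members rose (median 0.43) and with LT4 replicate 3 alone 4 rose (median 0.20). Immediate-early genes, which respond to growth signals within minutes, had no call over all genes among 20 members and 1 higher adjusted over the list alone, KLF4 (0.84, adjusted p = 0.117, chosen after its values were seen). The list's camera adjusted p was 0.216. It passed as higher without LT4 replicate 3 (0.0369, but adjusted p = 0.387 with an estimated correlation), with the length trend removed (0.029, likewise 0.486) and with the GC trend removed (0.0125, likewise 0.261).

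Targets of NRF2, the regulator of antioxidant genes, included 2 of 24 members that rose, TXNRD1 (thioredoxin reductase, from 151 ± 14.5 to 279 ± 22 CPM) and SLC7A11, and 6 rose adjusted over the list alone. ABCC3 (0.70, adjusted p = 0.104) and GCLM (0.70, adjusted p = 0.142) came next. NQO1, a widely used marker of NRF2, had 0.30 (SE 0.14, adjusted p = 0.363), with 0.13 in LT4 replicate 1 alone and 0.46 (adjusted p = 0.0467) in LT4 replicate 3 alone. The list's median was 0.22 with camera adjusted p = 0.00114 (higher), adjusted p = 0.254 with an estimated correlation and 0.0381 by fry, and 3 members rose with either LT4 library alone (medians 0.15 and 0.27). Among 9 aryl hydrocarbon receptor targets none passed over all genes by edgeR, DESeq2 called 1 (SLC7A5), and 3 rose adjusted over the list alone. These were TIPARP (0.82, SE 0.19, adjusted p = 0.109), CYP1A1 (0.81, SE 0.19, from 11 ± 0.552 to 18.7 ± 3.73 CPM) and the amino acid transporter SLC7A5. All 9 had positive values, though AHRR had only 0.006 and NFE2L2 0.05. CYP1B1, LRAT, ALDH3A1 and AHRR averaged 1.1 to 2.8 CPM with LT4, near the 1.31 CPM that 3 counts make in LT4 replicate 3. These 5 genes are named after their values were seen. The list's median was 0.73 with camera adjusted p = 0.00036 (higher), adjusted p = 0.254 with an estimated correlation and 0.0427 by fry. TIPARP passed with LT4 replicate 1 alone (1.05, adjusted p = 4.65e-05) and not with LT4 replicate 3 alone (0.41, adjusted p = 0.312). With LT4 replicate 1 alone 3 members rose (median 0.35) and with LT4 replicate 3 alone 1 did (median 0.46). The ferroptosis-related list had 2 of 17 members higher over all genes (CHAC1 and SLC7A11) and 4 adjusted over the list alone, which added SLC3A2 and ACSL4 (0.86, adjusted p = 0.124). Its camera adjusted p was 0.00141 (higher), with adjusted p = 0.254 with an estimated correlation and 0.0381 by fry, on a median of 0.09 (0.00 with LT4 replicate 1 alone and 0.14 with LT4 replicate 3 alone). It shared 3 members with the ATF4 list, and the other 14 gave a camera p of 0.8.

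Matrix proteases and adhesion genes, fixed because the study tested migration, had no call over all genes among 24 members (1 by limma voom and 2 by DESeq2, with 9 higher and 0 lower at an unadjusted p under 0.05), and 7 rose adjusted over the list alone. The smallest p was that of the integrin gene ITGB1 (0.81, SE 0.15, adjusted p = 0.0568), at 73.7 ± 9.3 CPM in controls and 129 ± 5.28 CPM with LT4. The protease genes ADAM9 (0.79, adjusted p = 0.0962) and PLAU, or urokinase (0.58, adjusted p = 0.113), and the integrin gene ITGA2 (0.64, adjusted p = 0.117) followed. The camera adjusted p was 0.000596 (higher, median 0.24), with adjusted p = 0.39 with an estimated correlation and 0.183 by fry. Without LT4 replicate 1 this call was not met (0.383), with 1 member higher and 1 lower, against 9 higher with LT4 replicate 1 alone. MMP9 had 4, 6 and 4 counts in controls 1, 2 and 3 and 0 in both LT4 libraries, too few to be tested. The epithelial-mesenchymal transition list (17 members) had no call over all genes by edgeR or limma voom and 1 by DESeq2. Adjusted over the list alone 3 were higher, among them TJP1 (0.58), and SPARC (-0.72) was lower, both named after their values were seen. By fry's mixed test the list's adjusted p was 0.0106. Its camera adjusted p was 0.299 with a median of -0.03 but a mean of 0.18 and a test direction of higher, and it passed as higher without LT4 replicate 3 (0.0369, but adjusted p = 0.539 with an estimated correlation). With LT4 replicate 1 alone its median was 0.21, with 3 members higher and 1 lower. With LT4 replicate 3 alone the test pointed lower (adjusted p = 0.666), the median was -0.26 and 0 members were higher and 2 lower. CDH1 (E-cadherin) had -0.34 (SE 0.16, adjusted p = 0.37), with -0.15 in LT4 replicate 1 alone and -0.64 (adjusted p = 0.0443) in LT4 replicate 3 alone. VIM (vimentin) had 0.83 (SE 0.32, adjusted p = 0.276), at 3.38 ± 0.985 CPM in controls and 6.13 ± 0.557 CPM with LT4.

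Other lists shifted down by small amounts, with no member past the threshold over all genes by edgeR in any of them. DESeq2 called 1 heat shock gene and none of the chaperone or interferon genes. The 18 heat shock genes had a median of -0.21 (camera adjusted p = 0.0136, 0.292 with an estimated correlation, 0.0427 by fry), with 1 lower adjusted over the list alone. That gene was HSPB1 (HSP27), at 1019 ± 73.9 CPM in controls and 617 ± 65.1 CPM with LT4 (-0.73, SE 0.13, adjusted p = 0.0568), while HSP90AA1 had 0.38 (adjusted p = 0.23). Its median was -0.15 with LT4 replicate 1 alone and -0.29 with LT4 replicate 3 alone, and without control 1 its adjusted p was 0.0511. The 23 unfolded protein response chaperones had a median of -0.11 (camera adjusted p = 0.0473, 0.366 with an estimated correlation, 0.106 by fry) with no call adjusted over the list alone, CALR (calreticulin) having -0.47 (adjusted p = 0.15). Their call was not met without control 1 (0.0832), without control 3 (0.0937) or without LT4 replicate 1 (0.161), nor with library totals only (0.0662), the stricter count minimum (0.0616), the length trend removed (0.0516) or equal depth (0.115). Among interferon-stimulated genes IFI6 (-0.81, adjusted p = 0.117) and OAS1 (-2.01, adjusted p = 0.118) were lower adjusted over the list alone. OAS1 was scarce, at 2.6 ± 0.524 CPM in controls. In LT4 replicate 3 it had 0.435 CPM, under the 1.31 CPM that 3 counts make there. The 21 members of this list had a median of -0.21 (camera adjusted p = 0.0136, 0.316 with an estimated correlation, 0.106 by fry). Their adjusted p was 0.0924 without LT4 replicate 1, 0.054 without LT4 replicate 3 and 0.0616 with the stricter count minimum, and their median was -0.17 with LT4 replicate 1 alone and -0.34 with LT4 replicate 3 alone.

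Among growth and metabolism lists, the 57 cytosolic ribosomal protein genes had a median of -0.14 (camera adjusted p = 0.00036, 0.593 with an estimated correlation, 0.419 by fry) and the 45 nuclear oxidative phosphorylation genes -0.13 (camera adjusted p = 0.00421, 0.581 with an estimated correlation, 0.421 by fry). Neither list had a member past the threshold over all genes or adjusted over the list alone by edgeR (5 and 4 lower and 0 higher at an unadjusted p under 0.05) or by DESeq2, and RPL5 (-0.52, adjusted p = 0.148) and ATP5PO (-0.57, adjusted p = 0.143) had the smallest p in each. Both calls were not met without LT4 replicate 1 (0.75 and 0.939), with medians of -0.26 and -0.32 in LT4 replicate 1 alone and -0.03 and -0.05 in LT4 replicate 3 alone. The 13 mitochondrially encoded mRNAs had no call over all genes and 3 lower adjusted over the list alone, MT-ND2 (-0.60, adjusted p = 0.0962), MT-ND1 (-0.57, adjusted p = 0.0962) and MT-ND6 (-1.30, adjusted p = 0.109). DESeq2 called 3 members of this list. Their camera adjusted p was 0.0146 (lower, median -0.07; -0.26 with LT4 replicate 3 alone but 0.08 with LT4 replicate 1 alone), with adjusted p = 0.577 with an estimated correlation and 0.326 by fry, and it was 0.0832 without control 1, 0.899 without LT4 replicate 3 and 0.278 with the length trend removed. The 25 cholesterol synthesis and SREBP2 targets had a median of -0.16 (camera adjusted p = 0.0187, 0.384 with an estimated correlation, 0.158 by fry), no call adjusted over the list alone, and an adjusted p of 0.316 without LT4 replicate 3 and 0.0922 at equal depth. LSS had -0.46 (adjusted p = 0.231) and SC5D 0.60 (adjusted p = 0.251). The 18 Wnt and beta-catenin targets had a median of -0.24 (camera adjusted p = 0.0302, 0.39 with an estimated correlation, 0.115 by fry), at -0.13 with LT4 replicate 1 alone and -0.37 with LT4 replicate 3 alone, and with CCND1 higher adjusted over the list alone and EPHB3 at -0.69 (adjusted p = 0.195). Their adjusted p was 0.0511 without control 1, 0.357 without LT4 replicate 3, 0.153 with the GC trend removed, 0.158 at equal depth and 0.0948 with the stricter count minimum, and DESeq2 called CCND1.

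**Figure D2:**
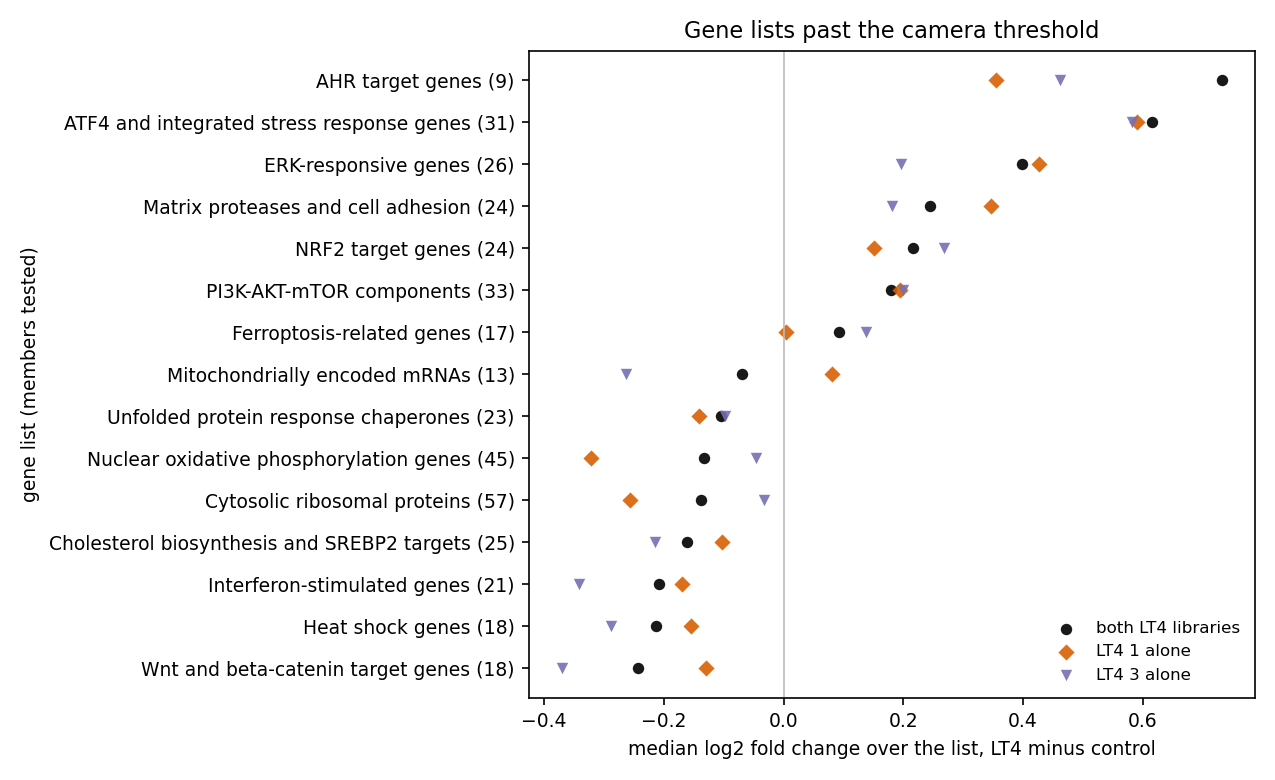
Median log2 fold change, LT4 minus control, over the members of gene lists past the camera threshold (number of members tested in brackets), for both LT4 libraries together and for each alone; not every such list is drawn, the histone list being left out because of its range. The ATF4 list lies at 0.62, with 0.59 for LT4 replicate 1 and 0.58 for LT4 replicate 3, while the ribosomal protein list lies at -0.26 for LT4 replicate 1 and -0.03 for LT4 replicate 3.

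CDKN1A, which encodes the cell cycle inhibitor p21, had a log2 fold change of 0.30 (SE 0.14, adjusted p = 0.359). It passed as higher with LT4 replicate 1 alone (0.48, adjusted p = 0.0339) and not with LT4 replicate 3 alone (0.10, adjusted p = 0.743). No call over all genes was made among 37 DNA replication and G1/S genes, 31 G2/M genes, 34 apoptosis regulators, 35 autophagy and lysosome genes or 31 MYC and ribosome biogenesis genes, with camera adjusted p of 0.213, 0.135, 0.319, 0.102 and 0.325. Adjusted over the list alone only 3 G2/M genes were higher, TOP2A (0.77), CENPF (0.86) and KIF11 (0.66), chosen after their values were seen. DESeq2 called 2 G2/M genes and none in the other 4 lists. MYC had -0.05 (SE 0.15, adjusted p = 0.908), with 0.11 in LT4 replicate 1 alone and -0.25 in LT4 replicate 3 alone. The G2/M list passed as higher without control 1 (0.0402, but adjusted p = 0.482 with an estimated correlation) and with the length trend removed (0.029, likewise 0.486). The autophagy list passed as lower with no count filter (0.0238, but adjusted p = 0.279 with an estimated correlation) and with the length trend removed (0.029, likewise 0.309). Camera adjusted p was 0.91 for hypoxia-induced genes (21 members), 0.196 for glycolysis (20), 0.213 for coenzyme Q synthesis (14), 0.711 for fatty acid synthesis (18), 0.0955 for fatty acid oxidation (19), 0.487 for NF-kB and inflammatory genes (11) and 0.725 for intestinal differentiation genes (9). None of these had a call over all genes, and adjusted over the list alone ACSL4 (fatty acid synthesis) and KLF4 (intestinal) were higher and COQ3 (coenzyme Q, -0.87, chosen after its values were seen) lower. DESeq2 and limma voom called 0 genes in these lists. By fry's mixed test the adjusted p was 0.0109 for apoptosis regulators and 0.0136 for coenzyme Q synthesis. It was 0.0126 for fatty acid oxidation and 0.0207 for intestinal differentiation genes. The other lists of this paragraph did not pass the mixed test. The fatty acid oxidation list passed as lower with no count filter (0.0333, but adjusted p = 0.279 with an estimated correlation). The fatty acid synthesis list passed as lower without LT4 replicate 1 (0.0292, but adjusted p = 0.543 with an estimated correlation). The glycolysis list passed as lower without LT4 replicate 1 (0.0134, but adjusted p = 0.739 with an estimated correlation) and without control 3 (0.0464, likewise 0.705). In the NF-kB list the median (-0.07) and the test pointed lower and the mean (0.11) higher, in the fatty acid synthesis list the mean (0.02) went against a median of -0.04, and for hypoxia-induced genes fry pointed higher.

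Few markers of other cell types were abundant enough to be tested. Of 16 fibroblast markers 4 were tested, all negative, with SPARC (-0.72) and TAGLN (-0.39), chosen after their values were seen, lower adjusted over the list alone and none over all genes; of 16 leukocyte markers 1 was tested and of 15 hepatocyte markers 3, with no call. With both LT4 libraries these lists had fewer than the 5 tested members set for camera. With a single LT4 library the fibroblast list was tested and passed as lower, with LT4 replicate 1 (camera adjusted p = 0.0106, adjusted p = 0.387 with an estimated correlation) and with LT4 replicate 3 (0.0222, adjusted p = 0.439 with an estimated correlation).

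Histone mRNAs and other RNAs that lack a poly(A) tail set LT4 replicate 3 apart. The replication-dependent histone genes together made up 624 CPM there, against 72.1, 107.9 and 89.1 CPM in controls 1, 2 and 3 and 80.9 CPM in LT4 replicate 1. None of 20 tested histone genes passed over all genes or adjusted over the list alone, while 17 passed as higher with LT4 replicate 3 alone and none with LT4 replicate 1 alone. H1-2, a linker histone gene, had a log2 fold change of 1.77 in LT4 replicate 3 alone and 0.10 in LT4 replicate 1 alone, H2BC5 2.12 and 0.29, H2BC12 1.56 and -0.10, and H2AC6 1.57 and 0.03. Most other members were scarcer and further apart: the median over the 20 was 3.69 in LT4 replicate 3 alone and -1.07 in LT4 replicate 1 alone, or 3.70 and -1.09 with members under 3 counts set to 3 counts (6 in LT4 replicate 1, 1 of them at 0). The list was past the camera threshold as higher with both libraries (adjusted p = 0.00114, 0.593 with an estimated correlation, 0.493 by fry) and as lower without LT4 replicate 3 (adjusted p = 0.00233, 0.583 with an estimated correlation). Nuclear-encoded ribosomal RNA genes made up 763 CPM in LT4 replicate 3 and 1.79 to 39.1 CPM in controls, 7SL RNA 553 CPM against 16.4 to 160 CPM, and mitochondrial ribosomal RNA 58300 CPM against 16790 to 19300 CPM. In LT4 replicate 1, 7SL RNA (13.2 CPM) and mitochondrial ribosomal RNA (9887 CPM) lay below every control. Control 2 had the highest values of the controls for the rRNA, snoRNA, snRNA, 7SL and histone classes.

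**Figure D3:**
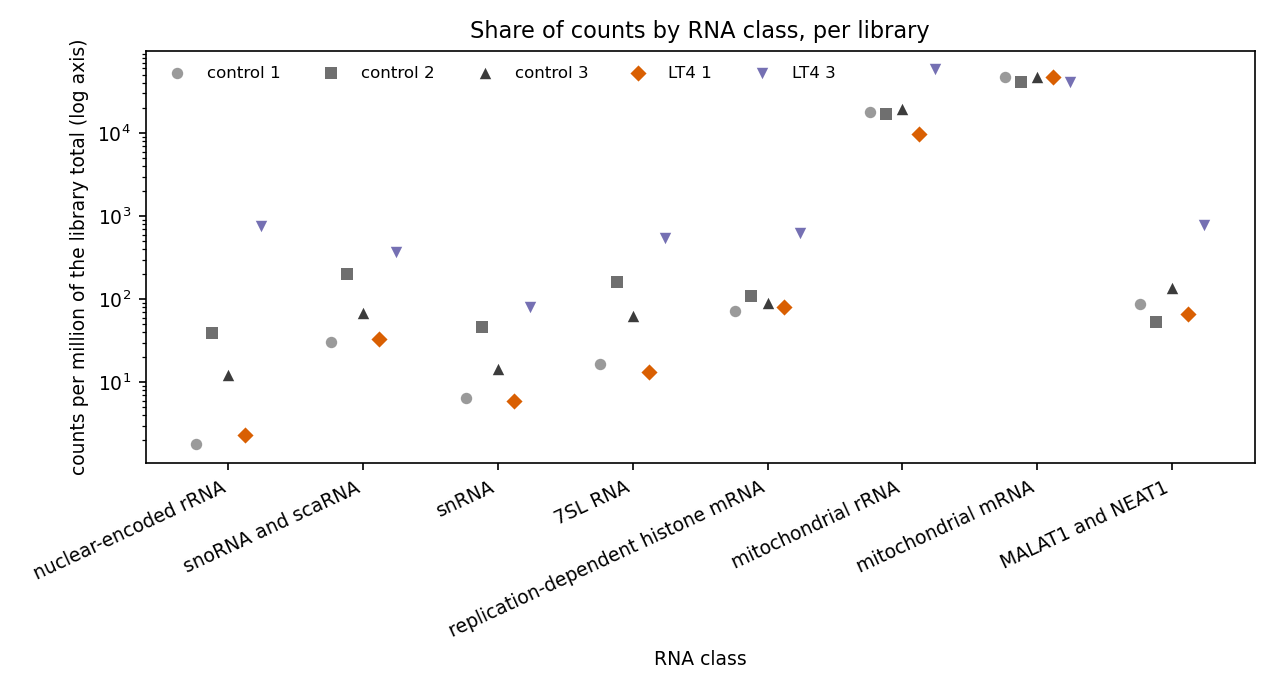
CPM of each library's total (log axis) taken by 8 RNA classes in the 5 libraries. LT4 replicate 3 has the highest value in each class except mitochondrial mRNA, for example 763 CPM of nuclear-encoded rRNA against 39.1 CPM in control 2.

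Each LT4 library was also set against the 3 controls alone, a comparison of that library and not of a group. Among 14130 genes tested in both, 351 were higher in LT4 replicate 1 and 349 in LT4 replicate 3, and 68 were higher in both. Lower genes numbered 175 and 229, with 17 lower in both, and 4 genes were called in opposite directions. Independent lists would share 8.67 higher and 2.84 lower genes, and 30 simulations of unchanged libraries against these controls shared 0.4 and 0.233 on average. The covariance of the log2 fold changes was 0.0408 against a simulated mean of 0.0138 (highest 0.0249), a difference of 0.027, and the correlation across genes was 0.289 against a simulated 0.206. The 3 controls are too few to be split into sets of 2 or more, so part of the excess may come from the shared controls. Both LT4 libraries also had a positive Spearman rho with gene length (0.449 in LT4 replicate 1 and 0.168 in LT4 replicate 3). How far such a shared trend adds to the overlap was not tested. The genes higher in both included CHAC1, SLC7A11, TRIB3, PCK2, PSAT1, STC2 and SLC3A2 of the ATF4 list. Most genes higher in both are not on that list, among them KIF21A, ROCK2 and AHNAK, named after their values were seen. The genes lower in both included CRABP2, KRT13, HSPB1, MT-ND1 and MT-ND2.

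In the authors' deposited table, which gives a value for 14970 genes, LT4 replicate 1 had 665 genes higher and 247 lower at an adjusted p under 0.05, and LT4 replicate 3 had 495 higher and 229 lower. There 122 genes were higher and 18 lower in both. Of the genes called here with edgeR in the single-library comparisons, 92.6% for LT4 replicate 1 and 90.5% for LT4 replicate 3 also passed in the authors' deposited table. For CHAC1 the authors' deposited table gives log2 fold changes of 1.96 and 1.95 for LT4 replicates 1 and 3, for SLC7A11 1.65 and 1.26, and for CRABP2 -0.92 and -1.18.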

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

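The tests with trends on gene length or GC content removed, with protein-coding genes only and at equal depth were chosen after the data were seen. All 19 called genes had the same direction in each of the 16 alternatives, and CHAC1 was past the threshold in all of them. Counts of called genes (19; 17 higher, 2 lower, 13 at least 2-fold) were 311 (229, 82 and 92) with no count filter, 83 (66, 17 and 26) by DESeq2, 80 (63, 17 and 26) with the GC trend removed and 1 (1, 0 and 1) at an adjusted p under 0.01. Lower genes numbered 5 among protein-coding genes only, 4 with the length trend removed and 4 by limma voom. Leaving out each library gave from 1 to 598 genes (1 to 369 higher, 0 to 229 lower, 1 to 253 at least 2-fold); with a single LT4 library left, the spread comes from the controls by construction. At equal depth 11 of the 19 genes passed, with fewer counts per gene by construction. The cause of the other differences was not tested. Spearman rho with GC content was -0.535 in LT4 replicate 3 and -0.0949 in LT4 replicate 1. In controls 1, 2 and 3, each set against the other controls, it was -0.257, 0.559 and -0.303.

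With the replicate number as a replicate block 427 genes passed (316 higher, 111 lower, 102 at least 2-fold). Control 2 shares its number with no LT4 library and so added nothing to this comparison. The spread was then judged from the pairs numbered 1 and 3 alone. Deviations from the group mean correlated at 0.363 across genes for the pair numbered 1 and 0.506 for the pair numbered 3, but with 2 LT4 libraries these deviations mirror each other, and the labels say nothing of pairing, so the libraries share only a number.

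Of 33 lists, 17 passed by camera, 0 with an estimated correlation and 5 by fry. The PI3K-AKT-mTOR list (0.0147) had adjusted p of 0.0616 with the stricter count minimum, 0.392 with the length trend removed, 0.12 at equal depth, 0.435 with an estimated correlation and 0.158 by fry, and 0.00334 to 0.471 with each library left out. The ERK-responsive list (1.77e-07) had 0.281 with an estimated correlation, 0.0983 by fry and 6.19e-11 to 0.0134 with each library left out. The histone list reversed without LT4 replicate 3 (0.00233, lower), and with each library left out its adjusted p ran from 1.08e-81 (without LT4 replicate 1) to 0.0182 (without control 1). The cause was not tested. Over all lists and alternatives 451 results kept their side of the threshold, 61 were no longer past it, 12 newly passed and 1 reversed. For named genes the numbers were 1145, 53, 131 and 0. Apart from the histone list without LT4 replicate 3, results past the threshold in both kept their direction. Those not past it may have turned. For example, the hypoxia list kept its direction in 10 of 14 alternatives. The depth of LT4 replicate 3 limits what can be seen of low genes.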

Other observations

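The tests of depth or RNA composition, of poly(A) selection and of the 5 further gene lists were chosen after the result was seen. Some of these lists hold genes already called here, such as NT5E and AXL or CRABP2 and KRT13. Their p-values describe the lists and are no independent support for a response. Aminoacyl-tRNA synthetase genes, which charge tRNAs with amino acids, had a median log2 fold change of 0.23 over 20 members (camera adjusted p = 0.0144 over 5 lists, 0.364 with an estimated correlation, 0.148 by fry), with both LT4 libraries above all controls for 12 and none past the threshold over all genes. YAP and TEAD target genes, of growth and cytoskeletal signalling, had a median of 0.24 over 22 members, 19 of them positive (camera adjusted p = 0.000307, 0.215 with an estimated correlation, 0.105 by fry). NT5E and AXL were the 2 that rose, and the median was 0.38 with LT4 replicate 1 alone and 0.03 with LT4 replicate 3 alone.

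Proteasome subunit genes had a median of -0.20 over 31 members, 3 of them positive (camera adjusted p = 0.00082, 0.312 with an estimated correlation, 0.161 by fry), at -0.32 with LT4 replicate 1 alone and -0.05 with LT4 replicate 3 alone, and none passed over all genes. ID genes and BMP targets had a median of -0.16 over 10 members (camera adjusted p = 0.0144, 0.215 with an estimated correlation, 0.000555 by fry), at -0.10 with LT4 replicate 1 alone and -0.37 with LT4 replicate 3 alone. ID3, an inhibitor of differentiation factors, had -0.71 (adjusted p = 0.0657). In retinoid genes ALDH1A3, which makes retinoic acid, rose while CRABP2 and KRT13 fell, and the list of 15 had a camera adjusted p of 0.0513.

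The ATF4 list was higher in each LT4 library alone by camera with a preset correlation but not with an estimated correlation (adjusted p = 0.359 for LT4 replicate 1 and 0.439 for LT4 replicate 3). Removing the gene-length trend left a median of 0.57, so that trend does not account for the rise. With LT4 replicate 1 alone the median lay at percentile 100 of 10000 random lists matched on expression, which argues against the depth or RNA composition of LT4 replicate 3. The largest shift of the list mean in a control against the other controls was 0.0367, against 0.653 and 0.56 in the LT4 libraries. A response to LT4 may underlie the rise, but this is a hypothesis that no test here addressed directly, and other differences in culture state were not tested.

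RNAs that lack a poly(A) tail took more of LT4 replicate 3 than of the other libraries. More cells in S phase would raise DNA replication genes, but the DNA replication and G1/S list had a median of -0.0255 there (95% bootstrap interval -0.171 to 0.0322, 37 genes). Less complete poly(A) selection in that library stays open: 5 of 5 RNA classes without a poly(A) tail had their highest share there, but this count restates the pattern and is no separate test of it. In LT4 replicate 1 histone mRNA (80.9 CPM) lay within the range of the controls (72.1 to 107.9 CPM) and 7SL RNA (13.2 CPM) below it (16.4 to 160 CPM). A treatment effect on these RNAs was not tested.

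Longer genes were higher in LT4 replicate 1 (Spearman rho with gene length 0.449 across 8746 genes, which are not independent replicates). Control 1 set against the other controls had a rho of 0.403, so a length bias that also varies between untreated libraries could produce the trend. In LT4 replicate 3 rho was 0.168, less than 0.5 times 0.449, the bound set beforehand against a treatment effect. At equal depth rho was 0.404 in LT4 replicate 1, and LT4 replicate 3 stayed under 0.5 times the lowest thinned value by 0.0293, so depth alone does not account for this. The bound took no account of the spread among controls (SD 0.33), so treatment and length bias cannot be told apart.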
